A study of Homo sapiens with 24 samples.

How the data were processed

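The study measured total RNA of laryngeal papillomas and adjacent tissue on Affymetrix arrays with 1 colour. RNA was isolated on spin columns and labelled with biotin during in vitro transcription, per the labels' protocols. The authors deposited 1 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. MAS5 combines the probe pairs of a probe set into 1 background-corrected signal and scales each array as a whole. The version and target value are not given in the sources used here. From the values, the 2% trimmed mean was about 1500 on every array of both tables, so the arrays were already scaled and no further normalization was applied. A paired t-test per gene in another program is named in the series' design text. Signals near background are noisy after MAS5, and a global scaling cannot show a change that all genes share.

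Groups and pair numbers were taken from the sample titles. The 20-array table held 10 complete pairs and was the only table in the main comparison. The 4-array table (pairs 7 and 8) came from another array type, was scaled array by array in the same way, and was used for the direction of within-pair differences and in 1 alternative that pooled all 12 pairs. That same-numbered samples come from the same patient rests on the design text. In a check of the pairing, the correlation of the deviations of same-numbered samples from their group means, within each spike-in set, ran from -0.05 to 0.32 (median 0.02, against -0.01 for samples of other numbers), and 4 of 10 papillomas matched their own number best. The correlation of 2 arrays lay between 0.576 and 0.935, and 0 columns were identical. The p-values of single genes and of the 3′/5′ ratios rest on the spread between pairs. Those of gene lists by camera with a preset correlation, described below, compare the genes of a list with other genes. They do not measure the spread between patients.

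Of 22277 probe sets, 62 were controls and were left out of tests. Of the others 19064 had 1 gene symbol, 1043 had several and 2108 had none, according to the platform annotation, and only those with 1 symbol were named. Of the 19064 symbols, 19052 matched a current gene record through the Entrez identifier and 0 symbols changed. Genes on the Y chromosome and the X-inactivation transcript (52 probe sets) were left out of every count and list. Each gene was represented by the probe set with the highest mean log2 signal over the 20 arrays, which gave 11939 genes. Genes in the lowest 40% of mean log2 signal were left out (floor 9.07, a signal of 536), leaving 7163. Where a named gene has other probe sets and these disagree in sign, the text says so for DST, GSTA1, PDGFRA and AQP1; TOP2A, JAG1, COL11A2 and HLA-C also had at least 1 other probe set of the opposite sign.

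Signals were transformed as log2(signal + 1). Papilloma was compared with adjacent tissue by limma 3.58.1 in R 4.3.3 (lmFit with the pair as a block, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 change means higher in papilloma, and an SE is the moderated standard error of the mean of 10 pairs. The 36 gene lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with the correlation estimated per list and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. Members of a list were counted as higher or lower at an adjusted p under 0.05 over all genes and, separately, adjusted over the list alone. The 3′/5′ ratios of the ACTB and GAPDH control probe sets were compared within pairs by an exact sign-flip permutation test. Plots were drawn with matplotlib 3.10.9.

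The text names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold that changed in the called direction in at least 8 of 10 pairs. Of each gene list it names up to 4 members past the threshold, those with the smallest p, or else up to 2 as values. The groups, tests, gene lists, rule for named genes and first alternatives were fixed before the data were examined. Alternatives covered the pair block, normalization, pseudocount, filter, variance prior, paired t-test, choice of probe set, tissue content covariates and the pairs used. The covariate for RNA integrity, the subsets by 3′/5′ gap and the subsets by spike-in signal were added after the data were seen. The sets of arrays were split at a cre control signal of 500000.

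The pipeline was tested on simulated data with the design of 10 pairs and 7163 genes. It recovered 49% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold, with 8 of 148 calls false. The simulated errors were independent between genes and held no difference in 3′/5′ ratio between the tissues. The share of false calls may therefore differ in the real data. Some members of the gene lists are not analysed here because no row of the tables used carries their symbol, and others fell below the filter, so each list is given with the number of genes tested.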

Results

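Gene expression was measured in 12 laryngeal papillomas and in 12 biopsies of adjacent laryngeal tissue, 1 of each per numbered pair. Recurrent respiratory papillomatosis is a disease in which benign squamous growths caused by human papillomavirus return in the airway. The design compared the tissues within pairs, so that differences between patients would not enter the comparison, and its title names immune dysregulation and tumour-associated genes as the question. Total RNA was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays. Pairs 1 to 6 and 9 to 12 (20 arrays) were in a table of 22277 probe sets, and pairs 7 and 8 (4 arrays) were in a table of another array type with 22283 probe sets. Every array had a 2% trimmed mean signal of about 1500. The number of arrays limits the precision of every value. No genome build is named for these values, so no positions are given.

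The 20 arrays formed 2 sets by the signal of the cre spike-in control, which is added in a fixed amount and is not a transcript of the tissue. It lay between 685953 and 1308100 on the 12 arrays of pairs 3, 4, 5, 6, 11 and 12 (the bright set) and between 99870.7 and 352055 on the 8 arrays of pairs 1, 2, 9 and 10 (the dim set). Both tissues of each pair were in the same set. Within every pair but pair 4 the cre signal was higher on the array of adjacent tissue. In pair 1 it was 352055 against 149757 in papilloma, and in pair 4 it was 685953 against 1040020. The cause was not tested. The 3′/5′ control ratios differed between the tissues. The log2 ratio of 3′ to 5′ control signal, which is higher in more degraded RNA and also depends on how the RNA was amplified and labelled, was 2.68 ± 1.55 (SD, n = 10) for ACTB in papilloma and 4.35 ± 1.40 in adjacent tissue. It was 1.07 ± 0.67 for GAPDH in papilloma and 2.32 ± 0.74 in adjacent tissue. The within-pair difference was -1.66 ± 1.26 (SD, n = 10 pairs) for ACTB and -1.25 ± 0.62 for GAPDH, below 0 in 10 of 10 pairs for both (exact two-sided sign-flip permutation test, p = 0.00195 for each, the smallest that 10 pairs can give). The mean ACTB difference was -1.40 in the 6 bright pairs (exact sign-flip test, p = 0.0312) and -2.06 in the 4 dim pairs, where the exact test cannot go below 0.125. For GAPDH the means were -1.20 and -1.32. The level of the ratio, averaged over both tissues of a pair, also differed between the sets. It was 4.50 ± 0.49 (SD, n = 6 pairs) in bright and 2.04 ± 0.36 (n = 4) in dim pairs for ACTB, a difference of 2.45, and for GAPDH it was higher by 1.15 in bright pairs (exact permutation test, two-sided, p = 0.00476 for each, the smallest that 210 splits can give). Each gene list below is also given for the 5 pairs with the smallest 3′/5′ gap, a choice made after the data were seen.

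In papilloma 8 of 26 genes of the cornified envelope and late squamous differentiation rose and 0 fell, and 7 of 21 genes of detoxification fell and 1 rose. With an estimated correlation the shift of neither list against other genes passed (camera, adjusted p = 0.184 and 0.195), and the detoxification list was not called in the 5 pairs with the smallest 3′/5′ gap (adjusted p = 0.0529) or with the 3′/5′ ratio as a covariate (0.704). Of 7163 genes tested in 10 pairs with limma, 336 passed an adjusted p of 0.05, of which 179 were higher and 157 lower in papilloma. Scaling each array to the same median gave 147 higher and 79 lower, the fit without the pair as a block 94 and 88, and the methods' paired t-test 32 and 40 after Benjamini-Hochberg adjustment. The change was at least 2-fold for 166 of them, 98 higher and 68 lower. The largest rise was that of KRT16, a keratin of activated epidermis, at 15.1-fold (log2 change 3.92 ± 0.68, SE, n = 10 pairs, adjusted p = 0.00886). The largest fall was that of CES1, a carboxylesterase that hydrolyses drugs and lipid esters, at 10.6-fold (log2 change -3.41 ± 0.45, adjusted p = 0.00287). CA2, a cytosolic carbonic anhydrase, rose 10.1-fold (3.33 ± 0.62, adjusted p = 0.0118), and KRT14, the keratin of basal cells, rose 8.45-fold (3.08 ± 0.46, adjusted p = 0.00361). The mean log2 signal of CES1 in papilloma (8.23) and of CA2 in adjacent tissue (7.84) lay under the filter floor of 9.07, where signals are noisy. The size of the CES1 and CA2 changes is therefore uncertain.

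The other 9 of the 12 largest rises were between 5.76-fold and 7.36-fold. They were COXFA4L2 (older symbol NDUFA4L2, log2 change 2.88), the filaggrin gene FLG (2.85), SPRR2B (2.79), the transglutaminase gene TGM1 (2.69), APOL1 (2.64), the plakophilin gene PKP1 (2.58), LY6D (2.55), the epithelial cytokine gene IL36G (2.54) and the kallikrein gene KLK12 (2.53), with FLG, SPRR2B and TGM1 belonging to the cornified envelope. The probe set of SPRR2B can bind near-identical transcripts of its family, so its signal is uncertain for that gene alone. The other 11 of the 12 largest falls were between 3.98-fold and 7.44-fold. They were the lysozyme gene LYZ (log2 change -2.89), ALDH3A1 (-2.81), ADH1C (-2.79), the decoy interleukin-1 receptor gene IL1R2 (-2.61), the immunoglobulin mu chain gene IGHM (-2.47), GSTA1 (-2.44), the clusterin gene CLU (-2.44), SELENBP1 (-2.12), GNG11 (-2.11), the prostaglandin D synthase gene PTGDS (-2.03) and AADAC (-1.99). GSTA1 shares sequence with other members of its family, and its second probe set had the opposite sign. The SE of the 24 changes lay between 0.33 and 0.68 and their adjusted p between 0.00287 and 0.0481. The mean log2 signal in papilloma also lay under the floor of 9.07 for ADH1C (8.36), IGHM (8.84), GNG11 (8.89) and PTGDS (8.96). The size of these falls is uncertain as well.

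**Figure D1:**
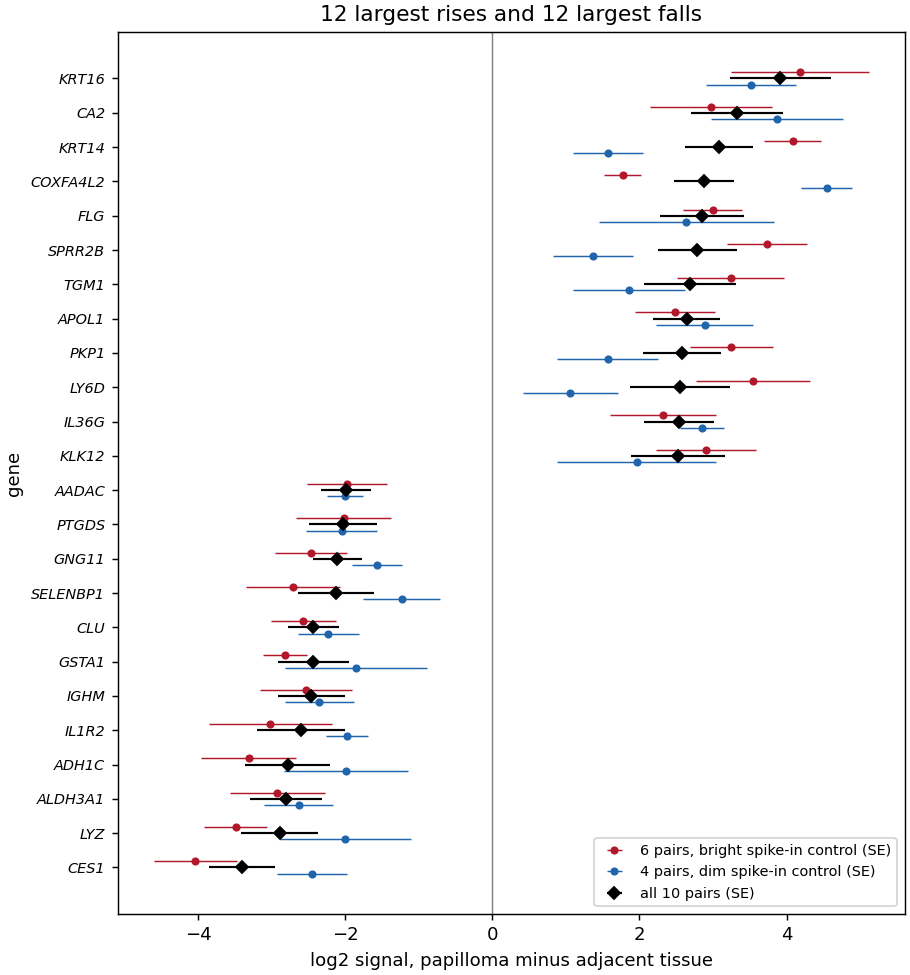
Log2 change (papilloma minus adjacent tissue, horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall. Black diamonds are the mean of 10 pairs, red points the 6 pairs with a bright spike-in control and blue points the 4 pairs with a dim one, each with its SE; KRT16 at 3.92 and CES1 at -3.41 are the extremes, and the 24 genes were selected on these 10 pairs.

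Within the 6 bright pairs alone limma called 61 genes (43 higher, 18 lower), of which 59 had the same sign in the dim pairs, with a median change in the called direction of 1.83 in the bright and 1.005 in the dim set. Within the 4 dim pairs it called 1 gene, with 1098 genes at an unadjusted p under 0.05. The change differed between the sets for 0 genes after adjustment (interaction term, limma) and for 224 of 7163 at an unadjusted p under 0.05. Across genes the changes of the 2 sets had a correlation of 0.47. With the mean 3′/5′ ratio of each array as a covariate, and equally in the 5 pairs with the smallest gap, limma called 0 genes, with 293 and 678 genes at an unadjusted p under 0.05. The median change of the 336 genes in their called direction, which was set on pairs that include these 5, was 0.71 with the covariate (median SE 0.42) and 0.87 in the 5 pairs (0.27), against 0.99 (0.22). Without pair 2, 11, 5, 12, 1 or 6 the count was 121, 138, 146, 163, 168 or 214, and 18 of the 24 largest changes passed whichever pair was left out, as did 37 of all 62 named genes past the threshold. Of the 24 largest changes 9 passed with the ciliated and glandular covariate, 13 with the fibroblast covariate, 5 by the methods' paired t-test and 0 with the 3′/5′ covariate or in the 5 pairs with the smallest gap.

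Keratinocyte genes rose in papilloma, and 0 of those tested fell. Of 10 basal keratinocyte genes tested 4 rose, namely KRT14, the linker gene DST (log2 change 1.92 ± 0.39, SE, n = 10 pairs), KRT5 (1.43 ± 0.33) and the integrin gene ITGA6 (0.77 ± 0.18), and 6 rose when adjusted over the list alone. In bright and dim pairs the changes were 4.08 and 1.57 (KRT14), 2.17 and 1.54 (DST) and 0.75 and 0.81 (ITGA6). KRT5 changed by 2.22 ± 0.26 in bright and by 0.24 ± 0.34 in dim pairs. DST has 7 other probe sets, of which 4 had the same sign, 0 of them at an unadjusted p under 0.05, and 1 had the opposite sign at such a p. Of 26 genes of the cornified envelope and late squamous differentiation 8 rose, among them SPRR2B, FLG, TGM1 and SPRR1B (2.46 ± 0.51), and 23 rose when adjusted over the list alone. Of 10 desmosome genes, which encode the junctions that hold keratinocytes together, 6 rose, among them PKP1, PERP (1.79 ± 0.37), DSG3 (1.54 ± 0.30) and DSC3 (1.24 ± 0.26), and 8 rose when adjusted over the list alone. Of 7 mucosal and stress keratins only KRT16 rose, also when adjusted over the list alone.

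The median log2 change was 0.81 for the basal list (0.67 in bright, 0.73 in dim pairs), 1.87 for the cornified list (2.59 and 0.99), 1.24 for the desmosome list (1.61 and 0.73) and 0.23 for the keratins (0.55 and -0.05). Against all other genes these lists were shifted upward (camera, preset correlation 0.01, adjusted over 36 lists), with adjusted p = 6.4e-05 for the basal, 1.3e-14 for the cornified, 4.9e-07 for the desmosome and 0.0455 for the keratin list. With an estimated correlation the adjusted p was 0.0745, 0.184, 0.104 and 0.219 in the same order, so that none passed. The list median lay above 0 in 10, 7, 8 and 7 of 10 pairs in the same order. The medians in the 5 pairs with the smallest 3′/5′ gap were 1.06, 1.19, 1.09 and 0.78. With the 3′/5′ covariate they were 1.22, 1.23, 0.90 and 1.02. All of these lists were called by camera at the preset correlation with the covariate (adjusted p = 5.1e-05, 5.1e-05, 0.000122 and 0.00787) and in the 5 pairs. The call of the keratin list was lost without pair 1 (adjusted p = 0.101), pair 3 (0.0975), pair 4 (0.0711), pair 5 (0.0885) or pair 6 (0.052).

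**Figure D2:**
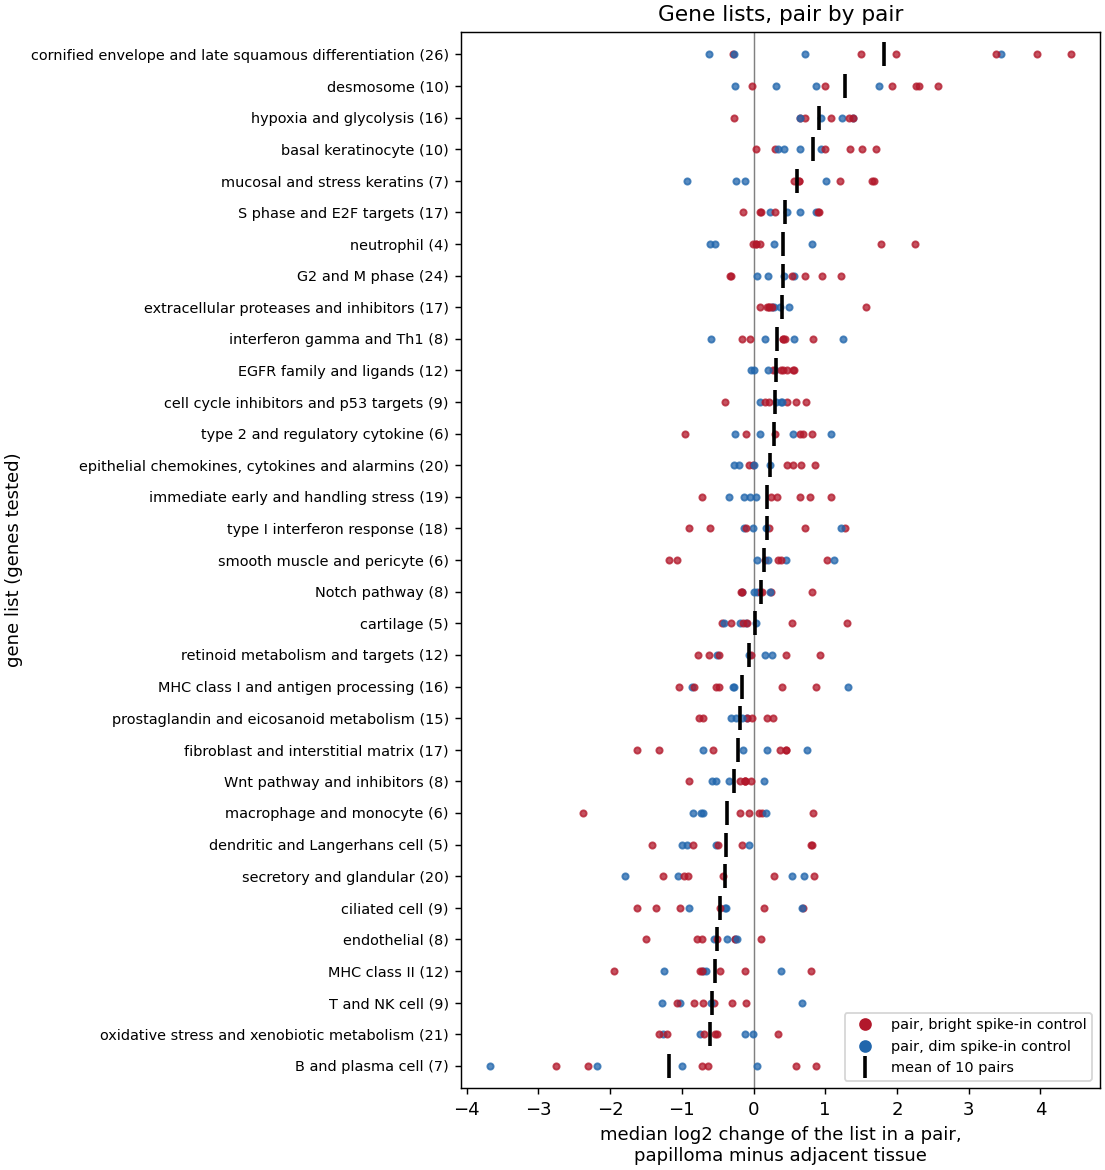
Median log2 change (papilloma minus adjacent tissue, horizontal axis) of each gene list with at least 3 genes tested, pair by pair; red and blue points are pairs with a bright or dim spike-in control and the black bar is the mean of 10 pairs. The cornified envelope list has the highest mean (1.82) and the B and plasma cell list the lowest (-1.18), and the points of both lists spread widely.

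The S phase and G2 and M phase lists had medians above 0 with 1 gene past the threshold. Of 17 S phase genes only MCM4, a subunit of the replicative helicase, rose (log2 change 0.88 ± 0.20, SE, n = 10 pairs, adjusted p = 0.0264), and 5 rose when adjusted over the list alone. Of 24 G2 and M phase genes 0 passed, on either adjustment. Those nearest were CCNB1 (0.60 ± 0.17, adjusted p = 0.0582) and TOP2A (0.54 ± 0.17, adjusted p = 0.0893), both above 0 in 10 of 10 pairs. Of 9 cell cycle inhibitor and p53 target genes only CDKN1A, which encodes the inhibitor p21, rose (1.40 ± 0.25, adjusted p = 0.00935), and 3 rose when adjusted over the list alone.

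The list medians were 0.52 for S phase (0.58 in bright, 0.66 in dim pairs), 0.59 for G2 and M phase (0.61 and 0.32) and 0.12 for the inhibitors (0.03 and 0.26). The camera test gave adjusted p = 3.3e-05, 0.000491 and 0.0588, and with an estimated correlation adjusted p = 0.104, 0.261 and 0.184. The 5 pairs with the smallest 3′/5′ gap gave medians of 0.56, 0.30 and 0.16, and there the G2 and M phase list was not called (adjusted p = 0.0908). The inhibitor list passed without pair 3 (adjusted p = 0.0349) or pair 12 (0.0333), and without the filter on low signals (0.00817).

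Single genes of growth factor, protease and differentiation pathways changed. Of 12 genes of the EGFR family and its ligands 2 rose, the small GTPase gene RAC1 (log2 change 0.59 ± 0.11, SE, n = 10 pairs) and the ligand gene TGFA (0.96 ± 0.25), and 5 rose when adjusted over the list alone. Of 17 extracellular protease and inhibitor genes 4 rose, the cathepsin gene CTSV (1.96 ± 0.24), the plasminogen activator gene PLAT (1.74 ± 0.36) and the serpin genes SERPINB3 (1.52 ± 0.32) and SERPINB5 (1.43 ± 0.21), and 7 rose when adjusted over the list alone. In the Notch list of 8 genes the ligand gene JAG1 (0.87 ± 0.17) and the receptor gene NOTCH3 (0.81 ± 0.22) rose, where 1 of 3 other JAG1 probe sets had the opposite sign at an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 1 fell. In the Wnt list of 8 genes the receptor gene FZD10 fell (-1.25 ± 0.30), also when adjusted over the list alone. In the retinoid list of 12 genes ALDH1A3, which makes retinoic acid, rose (1.41 ± 0.21) and the retinol dehydrogenase gene DHRS9 fell (-1.32 ± 0.35), and adjusted over the list alone 1 rose and 2 fell.

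The EGFR list (median 0.45, 0.55 in bright and 0.28 in dim pairs) and the protease list (0.45, 0.53 and 0.34) were shifted upward, with camera adjusted p = 0.00557 and 0.000456. With an estimated correlation the adjusted p was 0.0745 for both. The Notch, Wnt and retinoid lists had medians of 0.12, -0.08 and -0.10 and camera adjusted p = 0.407, 0.297 and 0.995. In the 5 pairs with the smallest 3′/5′ gap the medians were 0.51 (EGFR), 0.35 (protease), -0.09 (Notch), -0.29 (Wnt) and 0.07 (retinoid). With the 3′/5′ covariate DHRS9 had a log2 change of 0.23, of the opposite sign, and the retinoid list was shifted upward (adjusted p = 0.0232).

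Genes of glycolysis and of the response to low oxygen rose in papilloma. Of 16 tested 10 rose and 0 fell, and 13 rose when adjusted over the list alone. LDHA, the lactate dehydrogenase subunit, rose 3.01-fold (log2 change 1.59 ± 0.23, SE, n = 10 pairs, adjusted p = 0.00351). NDRG1 rose by 1.42 ± 0.25 and the angiogenic factor gene VEGFA by 1.40 ± 0.28, while the glucose transporter gene SLC2A1 rose by 0.98 ± 0.15. The list median was 0.93 (0.87 in bright, 1.11 in dim pairs), above 0 in 9 of 10 pairs, and 0.71 in the 5 pairs with the smallest 3′/5′ gap. The shift had a camera adjusted p = 3.4e-13, and 0.0745 with an estimated correlation.

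Genes of detoxification fell in papilloma, and among genes of airway secretion LYZ fell. In the list of 21 oxidative stress and xenobiotic metabolism genes 7 fell and 1 rose, and adjusted over the list alone 10 fell and 2 rose. Those with the smallest p were NQO1 (log2 change -1.28 ± 0.21, SE, n = 10 pairs), the aldehyde dehydrogenase gene ALDH3A1, the glutathione transferase gene GSTA1 and the alcohol dehydrogenase gene ADH1C, and the 1 that rose, named after its value was seen, was the aldo-keto reductase gene AKR1B10 (2.16 ± 0.53). Of 20 secretory and glandular genes only LYZ fell, and of 9 ciliated cell genes 0 passed, on either adjustment. SPA17 (-1.02 ± 0.37, adjusted p = 0.124) and SPAG16 (-0.58 ± 0.26, adjusted p = 0.216) came nearest in the ciliated list. Of 15 prostaglandin and eicosanoid genes only PTGDS fell, also when adjusted over the list alone.

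The xenobiotic list was shifted downward (median -0.61, with -0.68 in bright and -0.50 in dim pairs, camera adjusted p = 0.000544, and adjusted p = 0.195 with an estimated correlation). It was not called in the 5 pairs with the smallest 3′/5′ gap (median -0.23, adjusted p = 0.0529), nor with the 3′/5′ covariate, where its median was 0.03 (adjusted p = 0.704). The secretory (median -0.47), ciliated (-0.45) and prostaglandin (-0.16) lists had camera adjusted p = 0.137, 0.239 and 0.889, and medians of 0.06, -0.51 and -0.28 in those 5 pairs. The secretory list passed without pair 4 (adjusted p = 0.024), pair 9 (0.0301) or pair 10 (0.0438), and without the filter on low signals the secretory (0.047) and the ciliated list (0.0174) were called downward.

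The B and plasma cell, T and NK cell and MHC class II lists had negative medians, and few of their genes passed the threshold. Of 7 B and plasma cell genes IGHM fell 5.52-fold, the only one on either adjustment. Of 9 T and NK cell genes 0 passed over all genes and 1 fell when adjusted over the list alone. CD3D, a subunit of the T cell receptor complex, had a log2 change of -1.54 ± 0.45 (SE, n = 10 pairs, adjusted p = 0.0679) and TRBC1 of -0.67 ± 0.25 (adjusted p = 0.133). Of 12 MHC class II genes HLA-DPB1 fell (-0.87 ± 0.23, adjusted p = 0.0477), and 3 fell when adjusted over the list alone. In the neutrophil list of 4 genes S100A12, a calcium-binding alarmin, rose (1.53 ± 0.21, adjusted p = 0.00287), the only one on either adjustment.

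The B and plasma cell (median -0.84, with -0.69 in bright and -1.24 in dim pairs), T and NK cell (-0.67, -0.55 and -0.70) and MHC class II lists (-0.56, -0.68 and -0.35) were shifted downward, with camera adjusted p = 0.00911, 0.0277 and 0.027. With an estimated correlation the adjusted p was 0.276, 0.195 and 0.438. In the 5 pairs with the smallest 3′/5′ gap the medians were -1.18, -0.71 and -0.40 and all 3 lists were called (adjusted p = 0.000353, 0.00359 and 0.0342). With the 3′/5′ covariate the medians were -0.64, -0.45 and -0.11 and none of the lists was called (adjusted p = 0.228, 0.144 and 0.635). The list median lay below 0 in 7, 9 and 8 of 10 pairs. The T and NK cell call was lost without pair 2 (adjusted p = 0.055) or pair 3 (0.0628), and the MHC class II call without pair 1 (0.0551) or pair 5 (0.104). The T and NK cell and the B and plasma cell calls were both lost in the 6 bright pairs (adjusted p = 0.0622 and 0.051), with the lowest 60% of genes left out (0.0859 and 0.135), with the ciliated and glandular covariate (0.119 for both) and with the fibroblast covariate (0.0972 and 0.0714).

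The neutrophil list had a median of 0.27 and a camera adjusted p = 0.195. The macrophage and monocyte list (6 genes, median -0.42, adjusted p = 0.252), the dendritic and Langerhans cell list (5 genes, -0.16, adjusted p = 0.804), the MHC class I and antigen processing list (16 genes, -0.22, adjusted p = 0.195) and the red blood cell list (2 genes, 0.68, adjusted p = 0.378) had 0 genes past the threshold on either adjustment, as had TPSAB1, the 1 mast cell gene tested (-0.55 ± 0.35, SE, n = 10 pairs, adjusted p = 0.39). The smallest p in these lists were those of CSF1R (-0.60 ± 0.27) and C1QA (-0.84 ± 0.40), IRF8 (-0.54 ± 0.61) and CD83 (-0.41 ± 0.47), PSMB10 (-0.80 ± 0.43) and HLA-C (-0.55 ± 0.32), and HBD (0.66 ± 0.49) and HBB (0.69 ± 0.78). The MHC class I list passed without pair 9 (adjusted p = 0.0157). In the 5 pairs with the smallest 3′/5′ gap the neutrophil, macrophage, dendritic and MHC class I medians were -0.37, -0.64, -0.30 and -0.11, and those of the red blood cell and mast cell lists 1.07 and -0.75.

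Genes of the epithelial cytokine list rose and fell, and 1 type I interferon response gene rose. In the list of 20 epithelial chemokines, cytokines and alarmins IL36G and the defensin gene DEFB1 (log2 change 0.79 ± 0.20, SE, n = 10 pairs) rose, while IL1R2 and the T cell chemokine gene CCL5 (-1.54 ± 0.40) fell, and adjusted over the list alone 6 rose and 3 fell. Of 18 type I interferon response genes only IFI27 rose, 3.74-fold (1.90 ± 0.33, adjusted p = 0.00886), also when adjusted over the list alone. Of 8 interferon gamma and Th1 genes 0 passed on either adjustment, with IFNGR2 at 0.37 ± 0.17 and the chemokine gene CXCL10 at 0.78 ± 0.41. Of 6 type 2 and regulatory cytokine genes IL4R, the receptor of IL-4 and IL-13, rose (0.64 ± 0.16, adjusted p = 0.0341), also when adjusted over the list alone. Of 19 immediate early and handling stress genes KLF4 (0.72 ± 0.19) and MYC (1.46 ± 0.39) rose, and 3 rose when adjusted over the list alone.

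The list medians were 0.68 (epithelial cytokines), 0.01 (type I interferon), 0.27 (interferon gamma), 0.09 (type 2) and -0.07 (immediate early, whose mean was 0.11 and whose test pointed upward). The camera adjusted p were 0.0578, 0.195, 0.163, 0.498 and 0.252, so that none passed. In the 5 pairs with the smallest 3′/5′ gap the medians were 0.48, 0.03, 0.16, 0.18 and 0.33, and the immediate early list was called upward there (adjusted p = 0.004), as it was with the 3′/5′ covariate (median 0.63, adjusted p = 5.1e-05) and in the 6 bright pairs (0.0301). The epithelial cytokine list passed without pair 1 (adjusted p = 0.0481), pair 2 (0.0315), pair 3 (0.0436) or pair 5 (0.0462), the interferon gamma list without pair 1 (0.0405) and the type I interferon list without pair 11 (0.0448). Without the filter on low signals the epithelial cytokine (0.00817) and the type I interferon list (0.0316) were called upward.

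Stromal genes changed in part. Of 17 fibroblast and interstitial matrix genes 3 fell, also when adjusted over the list alone. They were CFD, complement factor D (log2 change -1.65 ± 0.30, SE, n = 10 pairs), the proteoglycan gene DCN (-1.20 ± 0.32) and the receptor gene PDGFRA (-1.83 ± 0.49), of which PDGFRA had 2 other probe sets of the opposite sign. Of 8 endothelial genes CD34 (-1.46 ± 0.35) and the water channel gene AQP1 (-1.18 ± 0.31) fell, and 3 fell when adjusted over the list alone. The second AQP1 probe set had the opposite sign. In the smooth muscle and pericyte list of 6 genes NOTCH3 rose, also when adjusted over the list alone. Of 5 cartilage and 2 skeletal muscle genes 0 passed on either adjustment, with COL11A2 at 0.15 ± 0.19 (its other probe set had the opposite sign at an unadjusted p under 0.05), COL9A2 at -0.23 ± 0.36, MB at -0.28 ± 0.60 and TNNT3 at -0.02 ± 0.26. The fibroblast, endothelial, smooth muscle, cartilage and skeletal muscle lists had camera adjusted p = 0.195, 0.171, 0.395, 0.864 and 0.908. Their medians were -0.21, -0.15, 0.00, 0.07 and -0.15, where the cartilage mean was -0.01. In the 5 pairs with the smallest 3′/5′ gap the fibroblast (median -0.52, adjusted p = 0.00523) and endothelial lists (-0.60, adjusted p = 0.00685) were called downward, as was the endothelial list without the filter on low signals (0.0106), and the smooth muscle, cartilage and skeletal muscle medians were -0.07, 0.27 and 0.13.

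The 2 pairs of the 4-array table, which took no part in the fit, showed the same genes in part. Of the 336 genes 199 had the called sign in both pairs, a share of 59.2% (exact Clopper-Pearson 95% interval 53.8 to 64.5, which treats genes as independent), against 27.9% of the 6827 genes not called. The sign held for 85.1% of the 336 genes in pair 7 and for 69.0% in pair 8, against 61.0% and 50.8% of the genes not called. The median change of the 336 genes in the called direction was 0.88 and 0.33. Of the 24 largest changes 20 kept their sign in both pairs. The exceptions were FLG (-1.75), TGM1 (-0.52) and SELENBP1 (0.60) in pair 8 and IL1R2 (0.61) in pair 7. KRT16 was higher by 7.09 and 1.73 and CES1 lower, at -4.80 and -3.53. The cornified envelope list had medians of 2.13 in pair 7 and -0.68 in pair 8, and the hypoxia and glycolysis list of 1.57 and 0.41. The B and plasma cell list had medians of -1.01 and -1.65, while the T and NK cell list (1.12 and -0.66) and the MHC class II list (0.59 and -0.65) were above 0 in pair 7. In a fit of all 12 pairs the calls of the last 2 lists were lost (adjusted p = 0.0575 and 0.0572). The 3′/5′ difference of pair 7 was -0.09 for ACTB and -0.34 for GAPDH, and that of pair 8 was -1.24 and -1.13. With 2 pairs no test of this table alone was made.

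**Figure D3:**
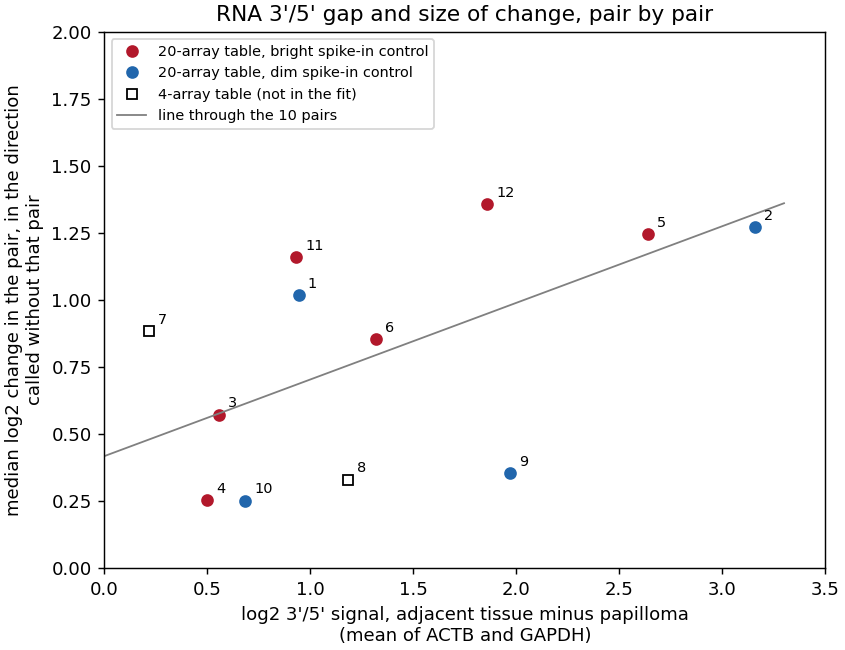
Median log2 change in each pair (vertical axis), over the genes called without that pair and in their called direction, against the pair's 3′/5′ gap (horizontal axis, log2, adjacent tissue minus papilloma). Circles are the 10 pairs of the 20-array table, squares pairs 7 and 8 with the 336 genes, and the grey line fitted to the circles has a slope of 0.29 ± 0.14 (SE). The genes differ between circles, from 121 for pair 2 to 366 for pair 4.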

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

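The test of RNA integrity on the called genes and the test of dilution on the immune lists, with each of its list choices, were chosen after the results they concern were seen.

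The first pattern is the count of 336 genes. In 100 swaps of the 2 tissues within pairs, the real arrangement included, 1 gave as many, the real one, and the highest other gave 38. A random assignment of the tissues is thus an unlikely source of this count. The swaps also break up the 3′/5′ gap, so they cannot separate a tissue difference from one of RNA quality. Lower RNA integrity of the adjacent tissue, which the 3′/5′ ratio does not separate from a difference in labelling, may account for part of the changes. Over genes called without a pair and measured in it, the median change rose with the 3′/5′ gap (slope 0.29 ± 0.14, SE, 10 pairs). The line met a gap of 0 at 0.42 ± 0.23, within 2 SE of 0. It lay beyond 2 SE at 0.53 ± 0.26 without pair 4, 0.42 ± 0.19 without pair 9 and 0.53 ± 0.25 without pair 10. With any other single pair left out it stayed within 2 SE of 0, lowest at 0.31 ± 0.23 without pair 11. The gene set differed from pair to pair, from 121 genes for pair 2 (gap 3.16) to 366 for pair 4 (gap 0.50). The slope therefore mixes the gap with the choice of genes. Over the fixed 336 genes the slope was 0.17 ± 0.10 and the value at a gap of 0 was 0.69 ± 0.17. Those genes were selected on the same 10 pairs, so neither line decides the question. The 3′/5′ covariate lowered the median change of the 336 genes from 0.99 to 0.71 and raised the median SE from 0.22 to 0.42, since the gap lies in 1 direction in all pairs, and 0 genes passed. The 5 pairs with the smallest gap, where 0 genes passed with fewer pairs, had a median change of 0.87 with a median SE of 0.27, over genes selected on pairs that include them. At the preset correlation camera kept 8 of its 13 list calls with the covariate and 11 in these 5 pairs. The basal, cornified, desmosome and keratin lists were kept both times. Outside the fit, pair 7 had a gap of 0.22 and a median change of the 336 genes of 0.88, against 1.18 and 0.33 in pair 8. The smaller gap thus went with the larger change there, but 2 pairs of another array type cannot decide the question. A biological difference between the tissues stays open, since the gap lies in 1 direction in all pairs.

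The second pattern is the rise of the hypoxia and glycolysis list. A higher share of squamous epithelium in the papilloma biopsies was tested by a line of the list's median per pair on that of the desmosome list, which met a desmosome change of 0 at 0.69 ± 0.26 (SE), more than 2 SE above 0, and at 1.05 ± 0.20 without pair 4. This cannot decide on that share. The desmosome median measures it with error, which flattens the slope (0.17 ± 0.16) and so raises the value at 0. The value also rests on pair 9, without which the line met 0 at 0.56 ± 0.33. A line on the 3′/5′ gap met 0 at 0.54 ± 0.29, less than 2 SE above 0, with a slope of 0.26 ± 0.17. It met 0 at 0.87 ± 0.22 without pair 4. With any other single pair left out it stayed within 2 SE of 0, lowest at 0.41 ± 0.30 without pair 11. RNA integrity and the tissue difference therefore cannot be told apart for this list with 10 pairs. With the 3′/5′ covariate the list's median was 0.55 and its shift was still called (adjusted p = 5.1e-05). In the 4-array table the list's median was 1.57 in pair 7 (gap 0.22) and 0.41 in pair 8 (gap 1.18), which 2 pairs cannot turn into a decision.

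The third pattern is the fall of the B and plasma cell and the T and NK cell lists. Dilution by squamous epithelium would lower immune and stromal lists alike only if the epithelium itself held none of their transcripts, which was not tested. The mean of the medians of all 5 immune cell lists with at least 3 genes minus that of the fibroblast, endothelial and smooth muscle medians was -0.23 ± 0.52 (SD, n = 10 pairs, below 0 in 6, exact two-sided sign-flip test, p = 0.203). Without the neutrophil list the difference was -0.44 ± 0.51 (exact p = 0.00781), and for the B and T cell lists alone, which were picked because they fell, -0.69 ± 0.81 (exact p = 0.0137), so that the outcome turns on the lists chosen and dilution stays open. A line of the mean of the B and T cell medians on the 3′/5′ gap met 0 at -0.52 ± 0.61 (SE) with a slope of -0.24 ± 0.36, and beyond 1.5 times from that at -1.04 without pair 2, -0.90 without pair 4, -0.33 without pair 1, -0.30 without pair 11 and -0.21 without pair 3, so that RNA integrity cannot be told apart from a tissue difference here. Both lists were called in the 5 pairs with the smallest gap (medians -1.18 and -0.71, camera adjusted p = 0.000353 and 0.00359). RNA integrity as the cause would give a smaller fall there. The lists were picked on pairs that include these, and camera does not measure the spread between pairs. Among these 5 pairs both medians were below 0 in pairs 1, 3, 10 and 11. In pair 4, with the smallest gap of the 10 (0.50), they were 0.86 and -0.11, against -3.67 and -1.28 in pair 2 (gap 3.16). In the 4-array table they were -1.01 and 1.12 in pair 7 (gap 0.22) and -1.65 and -0.66 in pair 8 (gap 1.18). A different site or depth of the 2 biopsies was not tested.

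Single pairs stood far from the other 9 in 11 of 118 series of within-pair values, and chance alone gives this in about 5% of series. In pair 5 the change of LY6D was 8.54 (others -0.57 to 3.95), that of TGFA 3.18 (0.21 to 1.51), that of JAG1 2.16 (0.31 to 1.26) and the median of the macrophage and monocyte list -2.38 (-0.85 to 0.82). In pair 12 AQP1 changed by -3.95 (-1.70 to 0.14), and the medians of the Notch and the protease lists were 0.81 (-0.17 to 0.25) and 1.56 (0.09 to 0.50). In pair 4 SPAG16 changed by -2.68 (-0.90 to 0.18), and the median of the hypoxia and glycolysis list was -0.27 (0.65 to 1.39). FLG changed by -2.37 in pair 9 (1.98 to 5.74 in the others), and ALDH3A1 by 1.70 in pair 3 (-4.62 to -1.61).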

How the results depend on the processing

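The covariate for RNA integrity and the subsets by 3′/5′ gap and by spike-in signal were chosen after the data were seen. For the main comparison (336 called, 179 higher, 157 lower, 166 at least 2-fold) these settings moved a count by more than 1.5 times, given in that order. Without the pair as a block limma called 182 (94, 88, 107), and it changed no gene list call. Without a variance trend it called 126 (69, 57, 94), with the ciliated and glandular covariate 68 (39, 29, 43) and with the fibroblast covariate 112 (67, 45, 72). With the RNA integrity covariate it called 0 (0, 0, 0; 293 at an unadjusted p under 0.05), and in the 5 pairs with the smallest 3′/5′ gap 0 (0, 0, 0; 678 unadjusted), while the 336 genes had a median change in the called direction of 0.71 and 0.87 there, against 0.99, with a median SE of 0.42 and 0.27, against 0.22. In 8 pairs without the 2 largest gaps it called 32 (23, 9, 28), in the 6 bright pairs 61 (43, 18, 58) and in the 4 dim pairs 1 (1, 0, 1), with fewer pairs in each. The methods' paired t-test called 72 (32, 40, 25) after Benjamini-Hochberg adjustment and 1429 (658, 771, 350) at its unadjusted threshold. Testing every probe set gave 310 higher of 488, with 282 at least 2-fold, and the mean of a gene's probe sets gave 217 with 78 lower. Scaling each array to the same median gave 226 with 79 lower, so that 65.0% of calls were higher against 53.3%. Apart from the construction of the smaller subsets, the cause was not tested.

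Leaving out each pair in turn gave 121 to 366 genes called, 78 to 204 higher, 43 to 162 lower and 83 to 197 at least 2-fold. It gave 12 to 15 lists called against 13, and p = 0.00391 for both 3′/5′ ratios. One pair of the 4-array table at a time gave 69.0% and 85.1% of the 336 genes with the called sign, against 59.2% in both, and genes changed at least 2-fold gave 70.5%. For genes not called the shares were 50.8% in pair 8 and 61.0% in pair 7. With an estimated correlation camera called 0 lists, with 13 called at the preset value, while fry called 13, of which 9 were the same. Without a filter camera called 19 lists, the 13 and 6 more, namely the inhibitor (adjusted p = 0.00817), epithelial cytokine (0.00817) and type I interferon lists (0.0316) upward and the endothelial (0.0106), ciliated (0.0174) and secretory lists (0.047) downward. The epithelial cytokine list gained its call under 10 settings in all besides those without 1 pair, the inhibitor list under 7, the type I interferon list under 6, the interferon gamma and immediate early lists under 3 each and the endothelial list under 3. The fibroblast list gained it in the 5 pairs with the smallest gap, the neutrophil list with the 60% filter (0.0183), the smooth muscle list with the fibroblast covariate (0.0386) and the Wnt list with fry (0.0413).

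List calls were lost as follows, besides those lost without 1 pair or with an estimated correlation. The T and NK cell and the B and plasma cell lists were not called with the lowest 60% of genes left out (adjusted p = 0.0859 and 0.135), in the 6 bright pairs (0.0622 and 0.051), with the ciliated and glandular (0.119 for both), the fibroblast (0.0972 and 0.0714) or the RNA integrity covariate (0.144 and 0.228). The T and NK cell and the MHC class II lists were not called with the skeletal muscle covariate (0.0521 and 0.0576), in 8 pairs (0.0633 and 0.113), in the 4 dim pairs (0.0505 and 0.101) and in 12 pairs of both tables (0.0575 and 0.0572). MHC class II was also lost with the ciliated and glandular (0.346), the fibroblast (0.215) and the RNA integrity covariate (0.635), and fry gave 0.128 for it and 0.058 for B and plasma cells. The keratin call was lost under quantile normalization, median scaling, the 60% filter, the 3 tissue covariates, the dim pairs and fry, the EGFR call in the dim pairs, the xenobiotic and G2 and M phase calls with the RNA integrity covariate and in the 5 pairs with the smallest gap, and the G2 and M phase call with fry.

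Under the RNA integrity covariate the change of DHRS9 reversed (log2 0.23). The retinoid list, which was not shifted in the main fit (camera adjusted p = 0.995), was called upward there (adjusted p = 0.0232). The cause was not tested. Quantile normalization, pseudocounts of 16 and 64, no filter, a filter on the lowest 60%, the robust variance prior, the skeletal muscle covariate and 12 pairs of both tables kept every count within 1.5 times. Over all settings, values of single named genes kept their direction and side of the threshold 1963 times, lost the call 662 times and gained it 11 times, and those of single lists did so 1004, 59 and 50 times. Signal over background limits genes near the floor of 536, and 10 pairs recovered 49% of simulated 2-fold changes.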

Other observations

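The genes in this part were chosen after their values were seen. The groups tested on their other members were picked because some members had changed in these same 10 pairs. The p-values of those groups are therefore not free of that choice. The smallest p of all 7163 genes was that of ID1, an inhibitor of basic helix-loop-helix transcription factors, which rose 3.82-fold (log2 change 1.93 ± 0.15, SE, n = 10 pairs, limma adjusted p = 2.3e-05) in 10 of 10 pairs, by 2.24 in bright and 1.47 in dim pairs. A line of its change on the 3′/5′ gap had a slope of 0.02 ± 0.19 and met a gap of 0 at 1.91 ± 0.32. Without 1 pair at a time that value lay between 1.76 and 2.17. ID1 was picked for its small p on these same pairs. Single genes that also rose were the actin-bundling FSCN1 (2.28 ± 0.32), the tropomyosin gene TPM4 (1.99 ± 0.27) and the ezrin relative MSN (0.78 ± 0.19). The collagen IV genes COL4A1 (2.39 ± 0.44) and COL4A2 (1.16 ± 0.26), whose products form basement membranes, rose as well. SPARCL1 fell (-1.87 ± 0.22), as did the first complement component genes C1S (-1.78 ± 0.36) and C1R (-0.98 ± 0.22).

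Beyond the hypoxia list, the glycolytic genes PKM (log2 change 1.30 ± 0.18, SE, n = 10 pairs), PGAM1 (0.76 ± 0.20) and GPI (0.74 ± 0.16) rose, as did the lipid droplet gene HILPDA (1.56 ± 0.39). The fatty acid desaturase genes SCD (2.20 ± 0.35) and FADS2 (1.71 ± 0.36) rose in 10 of 10 pairs.

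SQLE (log2 change 1.48 ± 0.26, SE, n = 10 pairs), DHCR7 (1.40 ± 0.33) and EBP (1.35 ± 0.25), enzymes of cholesterol synthesis, were among the genes that rose. The hypothesis that the pathway as a whole may be higher in papilloma was tested on its other 13 genes. Of these 11 were above 0, with a median of 0.49, and 0 passed by limma on their own. Camera gave p = 6.4e-05 with the preset correlation and p = 0.0792 with an estimated correlation, and the median over pairs was 0.41 ± 0.48 (SD, n = 10 pairs, above 0 in 8, exact two-sided sign-flip test, p = 0.0293). The value with an estimated correlation leaves the hypothesis open, and its relation to the 3′/5′ gap was not tested.

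NDUFB8 (log2 change -0.72 ± 0.15, SE, n = 10 pairs), SDHA (-0.62 ± 0.16), COX7A2 (-0.55 ± 0.13) and NDUFB2 (-0.42 ± 0.11), subunits of the mitochondrial respiratory chain, were among the genes that fell. The hypothesis that respiratory chain genes may be lower as a group was tested on the other 62 subunit genes. Of these 49 were below 0, with a median of -0.16, and 0 passed by limma on their own. Camera gave p = 0.000225 with the preset correlation and p = 0.282 with an estimated correlation. The median over pairs was -0.16 ± 0.27 (SD, n = 10 pairs, below 0 in 7, exact two-sided sign-flip test, p = 0.0918), so that a shift of the whole group was not shown against the spread between pairs.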
